A study of Homo sapiens with 6 samples.

How the data were processed

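Total RNA of untreated cells was extracted with Trizol, labelled with biotin and hybridised to Affymetrix Human Genome U133 arrays (A set), which measure each transcript with sets of short probes, per the labels' protocols. The deposited values are intensity values on a linear scale, 1 signal for each probe set and array, made with MAS5 per the submitters' processing notes; its version is not given in the sources used here. MAS5 summarises each array by itself after subtracting a mismatch-based background, so low signals scatter widely. The 2% trimmed mean was 500.2 on each of the 6 arrays, so they were used as deposited. Detection calls are not given in the sources used here. As a level of background, the 95th percentile of 27 bacterial control probe sets over all arrays was 81.9. Where an array on the dimmer side of a comparison lay under it, a named gene is given by its signals or as a lower bound of the fold, in place of a log2 difference. The bound comes from geometric mean signals with the dimmer side's signals raised to that level. This rule was widened after the values had been seen, from genes with all dimmer arrays under the level, and the count of ordered genes with low signals raised to that level was added then too. Values without 1 array follow where they lay over 1.5-fold from the value with all. Genes are ranked on the log2 differences of the tests.

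Of 22215 probe sets, 19065 had 1 gene symbol in the array's annotation, 1043 had several and 2107 had none. Symbols were updated through gene identifiers, of which 12 had no match. Each gene was represented by its probe set with the highest mean log2 signal over the 6 arrays. A gene was tested if its signal lay above the array's own median on at least 2 arrays, which left 7724 of 11964 genes. Tests ran on log2(signal + 29), the pseudocount being the 20th percentile of all signals, and a fold on that scale understates the difference of dim genes. limma 3.58.1 in R 4.3.3 fitted the 4 cell lines as a factor with an intensity trend in the variance, with 2 residual degrees of freedom and 6.87 from the prior. Lines with 1 array were assumed to vary like those with 2. A fit without 1 array of L-1236 or L-540 kept 1 residual degree of freedom, from the pair of the other line. Calls lost or gained in such a fit therefore also reflect which pair gave the spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1, and "not called" means that either condition failed. Differences are L-1236 minus L-540 unless another direction is named.

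The contrasts were L-1236 against L-540, L-1236 against the mean of KM-H2 and HDLM-2, and that mean against L-540. Genes ordered with sensitivity were counted, a slope over the 4 line means was tested with limma, and KM-H2 and HDLM-2 were compared as values. The 25 gene lists, with 766 genes of which 681 were annotated on the array, were tested with limma's camera at a preset correlation of 0.0100, again with an estimated correlation, and with fry. With an estimated correlation camera takes its degrees of freedom from the residuals, here 2, and had little power to call any list. The Hodgkin and Reed-Sternberg list, estimated at 0.0132, moved from an unadjusted camera p of 0.00224 to 0.0976. Camera compares a list with other genes, while fry asks only whether the list's own genes differ. Named genes were the 10 largest called differences in each direction between L-1236 and L-540, the 5 largest in each direction of the other contrasts, of the ordered genes and of KM-H2 against HDLM-2, up to 4 called members of each list or, with fewer than 2 called, the 2 of smallest adjusted p, and 10 genes fixed by name (TNFRSF8, PRAME, ABCB1, ABCC1, ABCG2, BCL2, MCL1, BAX, TOP2A and GSTP1) where tested. Design, lists, rule and alternatives were fixed before the data were examined. The alternatives were no filter or a stricter one, other pseudocounts, quantile normalization or median scaling, other uses of the probe sets, no intensity trend, other thresholds, a replicate block, sensitivity class as the factor, and leaving out each array.

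Some choices were changed after results had been seen. Fits without 1 array first chose, against the design's wording, filter and probe sets again on the 5 arrays left, which dropped or replaced genes bright in 1 line. They were then fixed on all 6 arrays as the design states, and the counts for L-1236 against L-540 moved from 1198 to 1202 without L-1236 array 2, 927 to 928 without L-1236 array 1, 828 to 820 without L-540 array 1, 975 to 935 without L-540 array 2, 1261 to 1259 without KM-H2 and 1275 to 1270 without HDLM-2. A list of hypoxia and glycolysis genes was added after genes had been seen to differ between the arrays of a line. Its test, the test of a culture state and the estimate of mixture were each revised or joined by another after the first outcome had been seen, and both outcomes are given.

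The procedure was tested on simulated data for L-1236 against L-540 with 7724 genes. It recovered 10 of 67 genes changed by a log2 difference of 1, 54 of 67 changed by 2 and 62 of 66 changed by 3, and called 8 of 7374 unchanged genes. Noise was drawn independently for each gene and array from the variance that the test assumes, and the other lines were simulated alike. The count of unchanged genes called therefore does not measure the rate of false calls in the real data. A log2 difference of 1 lies on the threshold for calling. Control probe sets and probe sets without exactly 1 gene symbol were left out of the gene tests.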

Results

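The expression of genes was measured on Affymetrix Human Genome U133 arrays (A set) in 4 untreated cell lines of Hodgkin's lymphoma, a lymphoma whose malignant Reed-Sternberg cells mostly descend from B cells. Per the labels, L-1236 had the lowest sensitivity to cytotoxic chemotherapy and L-540 the highest, and each had 2 arrays. KM-H2 and HDLM-2 had intermediate sensitivity and 1 array each. The 6 arrays had medians between 144 and 166 signal units, and 7724 genes passed the filter on low signals. Across these genes, which are not independent replicates, the arrays of L-1236 had a Pearson r of 0.940 with each other and those of L-540 a Pearson r of 0.943, while arrays of different lines lay between 0.678 and 0.787. The highest of the values between lines was that of the second arrays of L-1236 and L-540. The number of arrays limits the precision of every value below. The labels do not say whether the arrays of a line came from separate cultures, so p-values measured only the spread between these arrays, which may be technical.

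The comparison of L-1236 with L-540 set the least against the most drug-sensitive line. LTA, the cytokine lymphotoxin alpha, had a signal of 9795 ± 1284 (SD, n = 2) in L-1236 and 31.4 ± 8.24 (SD, n = 2) in L-540, at least 119-fold higher (limma adjusted p = 1.03e-06). CCL2, a chemokine that attracts monocytes, stood at 5938 ± 935 (SD, n = 2) against 9.15 ± 1.10 (SD, n = 2), at least 72.0-fold higher (limma adjusted p = 1.09e-05). FCER1A, the alpha chain of the high-affinity IgE receptor, was at least 109-fold higher in L-1236 and BEX3 at least 101-fold higher (limma adjusted p = 7.90e-06 and 1.89e-05). BASP1, a membrane-bound signalling protein, had a signal of 17739 ± 127 (SD, n = 2) in L-1236 and 124 ± 4.42 (SD, n = 2) in L-540. NDST4, an enzyme of heparan sulfate synthesis, was at least 74.6-fold higher in L-1236. MARCKS, a substrate of protein kinase C (at least 31.6-fold), and RRAGD, a GTPase that activates mTORC1 (at least 39.9-fold), were also higher in L-1236. So were RGS2 (at least 41.2-fold, 27.3-fold and 62.2-fold without L-1236 array 1 and 2) and RGS1 (at least 30.5-fold), regulators of G-protein signalling.

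Among the 10 largest differences toward L-540 in the fit of all arrays was GLUL, glutamine synthetase, which had a signal of 4908 ± 3211 (SD, n = 2) in L-540 and 192 ± 226 (SD, n = 2) in L-1236 (limma adjusted p = 0.00288). The bound was 25.6-fold, 12.4-fold and 53.1-fold without L-1236 array 1 and 2, 15.5-fold and 42.3-fold without L-540 array 1 and 2. PLA2G2D, a secreted phospholipase, was at least 18.8-fold higher in L-540 and RNF144A, a ubiquitin ligase, at least 14.0-fold higher (limma adjusted p = 2.43e-04 and 4.75e-04). PRDX2, a peroxiredoxin that removes hydrogen peroxide, was higher in L-540 (at least 17.8-fold, 9.33-fold and 33.9-fold without L-1236 array 1 and 2), as was PON2, a paraoxonase (at least 16.9-fold). IL26, a cytokine of T cells (at least 17.1-fold, 10.9-fold and 26.8-fold without L-540 array 1 and 2), and G0S2, an inhibitor of lipolysis (at least 26.5-fold, 10.9-fold and 64.4-fold without L-1236 array 1 and 2), stood higher there too. The others of the 10 were NKG7, a protein of cytotoxic granules (at least 16.6-fold, 5.20-fold and 53.2-fold without L-1236 array 1 and 2), HOPX (at least 19.0-fold, 4.34-fold and 83.3-fold without L-1236 array 1 and 2) and CYTIP (at least 22.7-fold, 6.69-fold and 77.1-fold without L-1236 array 1 and 2). Without L-1236 array 2 the bounds of HOPX, CYTIP and NKG7 passed that of GLUL, but lower bounds do not rank genes. On L-1236 arrays 1 and 2 NKG7 read 7.82 and 839, HOPX 16.0 and 1573, and CYTIP 39.5 and 944. Neither NKG7 nor HOPX was called without L-540 array 1 or without L-540 array 2, and CYTIP was not called without L-540 array 1. The spread in those fits came from the 2 L-1236 arrays. TNFRSF8, which encodes the Hodgkin marker CD30, was also higher in L-540, at 11209 ± 80.2 (SD, n = 2), and read 379 and 2559 on the L-1236 arrays (limma adjusted p = 0.00740). Its difference was log2 -3.45 ± 0.66 SE, -2.12 and -4.78 without L-1236 array 1 and 2.

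**Figure D1:**
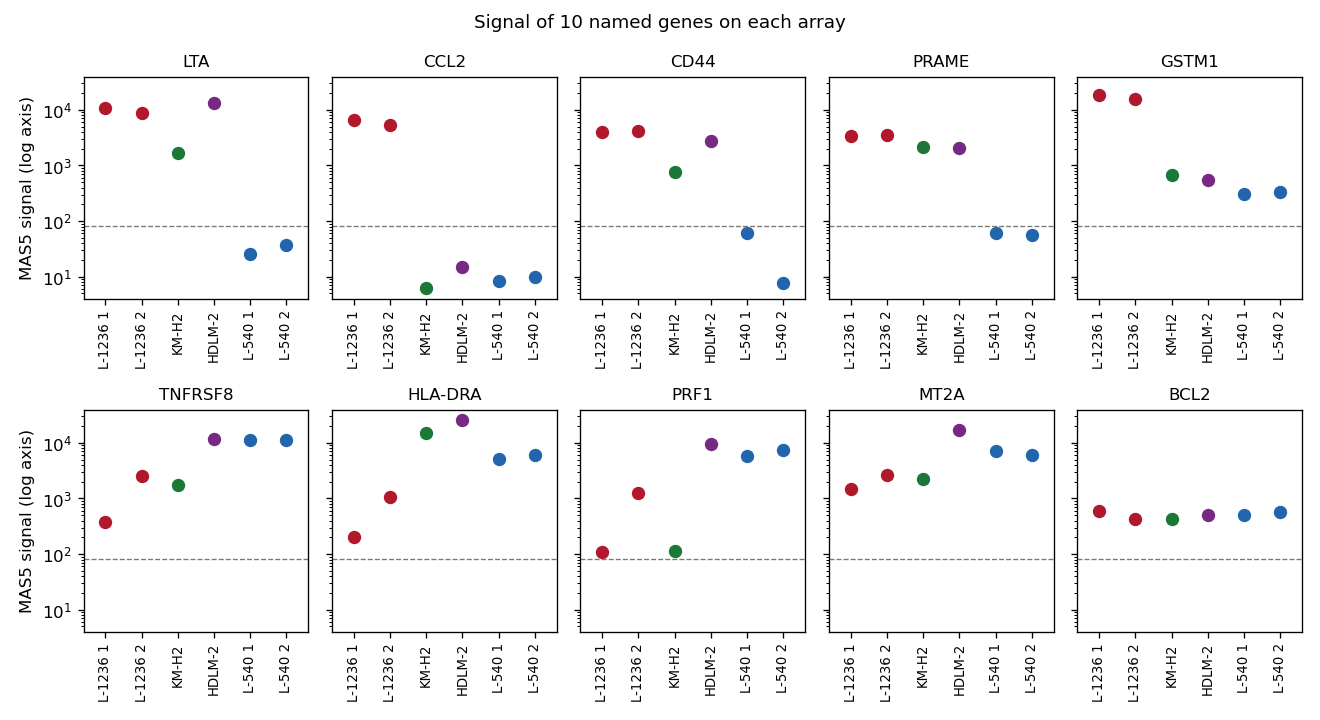
MAS5 signal (log axis) of 10 named genes on the 6 arrays, with 1 point per array and a dashed line at 81.9, the 95th percentile of the bacterial control probe sets. LTA, CCL2, CD44, PRAME and GSTM1 were higher on both L-1236 arrays than on both L-540 arrays, TNFRSF8, HLA-DRA, PRF1 and MT2A were lower, and BCL2 read 592 and 423 in L-1236 against 541 ± 54.0 (SD, n = 2) in L-540.

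In all, 1259 of 7724 genes differed between L-1236 and L-540, 703 higher in L-1236 and 556 higher in L-540. Without L-1236 array 2, on which genes of L-540 stood higher than on array 1, 1202 genes differed, 585 higher in L-1236 and 617 higher in L-540, and 995 genes were called in both fits. The count was 820 without L-540 array 1, with 295 higher in L-540, and 365 genes were higher in L-540 without L-540 array 2. In the fits without an array the spread came only from the line that kept both of its arrays. With sensitivity class in place of cell line, so that the difference between KM-H2 and HDLM-2 counted as spread, 151 genes were called.

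Cytokine genes were higher in L-1236, set against other genes, by camera at its preset correlation. They also differed as a group by fry, which makes no comparison with other genes (fry adjusted p = 0.00623). Camera with an estimated correlation called neither this list nor any other, but with 2 degrees of freedom it had little power to do so. The list of interleukins and chemokines also holds the cytokine genes CSF1, LTA, LTB, TNF and TGFB1. Of its 19 tested genes, 9 were higher in L-1236, 2 were higher in L-540 and 8 were not called, with 12 called when adjusted over the list alone (camera adjusted p = 0.00443, adjusted p = 0.683 with an estimated correlation). Beside LTA and CCL2, those higher in L-1236 included IL6 (at least 14.1-fold) and CCL17, a chemokine that attracts T helper cells (at least 8.67-fold, 4.74-fold and 15.9-fold without L-1236 array 1 and 2). Of 27 tested Hodgkin and Reed-Sternberg cell genes, 13 were higher in L-1236, 6 were higher in L-540 and 8 were not called, with 21 called when adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.683 with an estimated correlation). This list shares CSF1, IL6, IL13, LTA, CCL5, CCL17 and CCL22 with that of interleukins and chemokines, so the results of these lists overlap. IL13RA1, a chain of the interleukin 13 receptor, was higher in L-1236 (at least 30.8-fold), and CD70, a ligand of the tumour necrosis factor family, was higher in L-540 (log2 -3.70 ± 0.38 SE, -3.07 and -4.34 without L-540 array 1 and 2). This list was not called without L-1236 array 2, where camera gave an adjusted p of 0.0770. Of 9 tested cancer-testis antigens, 2 were higher in L-1236, 0 were higher in L-540 and 7 were not called, with 3 called when adjusted over the list alone (camera adjusted p = 0.0255, adjusted p = 0.683 with an estimated correlation). PRAME, a tumour antigen, had a signal of 3415 ± 96.8 (SD, n = 2) in L-1236, at least 41.7-fold above that of L-540, and MAGEB2 was also higher (at least 19.0-fold). The camera adjusted p of the cancer-testis list was 0.0502 without L-1236 array 1 and 0.0655 without L-540 array 2.

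Genes of antigen presentation to helper T cells, and metallothioneins, were lower in L-1236, set against other genes, by camera at its preset correlation only. Their estimated correlations were 0.474 and 0.755, and fry gave adjusted p of 0.198 and 0.203. Of 15 tested MHC class II genes, 0 were higher in L-1236, 7 were higher in L-540 and 8 were not called, with 7 called when adjusted over the list alone (camera adjusted p = 0.00220, adjusted p = 0.683 with an estimated correlation). HLA-DRA had a signal of 5550.3 ± 717 (SD, n = 2) in L-540 and read 204 and 1063 on the L-1236 arrays. Its difference was log2 -3.46 ± 0.56 SE, -2.35 and -4.57 without L-1236 array 1 and 2. HLA-DRB4 was at least 4.97-fold and HLA-DQA1 at least 4.61-fold higher in L-540. HLA-DRB1 was higher in L-540 (log2 -2.48 ± 0.56 SE, -1.37 and -3.60 without L-1236 array 1 and 2). It had limma adjusted p of 0.0713 and 0.0664 without either L-540 array, and the probe sets of these related genes can share target sequence. Without L-1236 array 2, 10 of the list were higher in L-540 (camera adjusted p = 8.56e-07, adjusted p = 0.685 with an estimated correlation). Of 8 tested genes of the list of metallothioneins, metal-binding proteins, and their regulator MTF1, 0 were higher in L-1236, 4 were higher in L-540 and 4 were not called, with 4 called when adjusted over the list alone (camera adjusted p = 0.00388, adjusted p = 0.683 with an estimated correlation). MT2A read 1455 and 2696 in L-1236 and 6574 ± 833 (SD, n = 2) in L-540, a log2 difference of -1.71 ± 0.28 (SE). MT1X was higher in L-540 (log2 -2.31 ± 0.46 SE, -1.51 and -3.10 without L-1236 array 1 and 2), with a limma adjusted p of 0.0603 without L-540 array 2. The metallothioneins are also near-identical in sequence.

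Genes of the JAK-STAT pathway and of the interferon response were lower in L-1236, set against other genes, by camera at its preset correlation only. Their estimated correlations were 0.0734 and 0.203, and fry gave adjusted p of 0.104 and 0.222. Of 26 tested JAK-STAT pathway genes, 1 was higher in L-1236, 7 were higher in L-540 and 18 were not called, with 8 called when adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.683 with an estimated correlation). PIM1, a survival kinase, read 135 and 667 in L-1236 and 3394 ± 798 (SD, n = 2) in L-540, and STAT5B was higher in L-540 as well (log2 -1.74 ± 0.23 SE). The difference of PIM1 was log2 -3.32 ± 0.56 SE, -2.28 and -4.36 without L-1236 array 1 and 2. JAK2, a kinase of cytokine receptors, was higher in L-1236, with 1.87 ± 0.34 (SE). Of 33 tested interferon response genes, 2 were higher in L-1236, 12 were higher in L-540 and 19 were not called, with 15 called when adjusted over the list alone (camera adjusted p = 0.0386, adjusted p = 0.707 with an estimated correlation). IFITM2, a membrane protein that limits virus entry, was higher in L-540 (log2 -3.19 ± 0.57 SE, -2.08 and -4.30 without L-1236 array 1 and 2). IFI16, a sensor of DNA (log2 -3.13 ± 0.37 SE, -2.54 and -3.73 without L-1236 array 1 and 2), and GBP2 (log2 -2.48 ± 0.34 SE) were too. On the L-1236 arrays IFITM2 read 433 and 2124. The camera adjusted p of the interferon list was 0.0770 without L-1236 array 1 and 0.0771 without L-540 array 2.

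**Figure D2:**
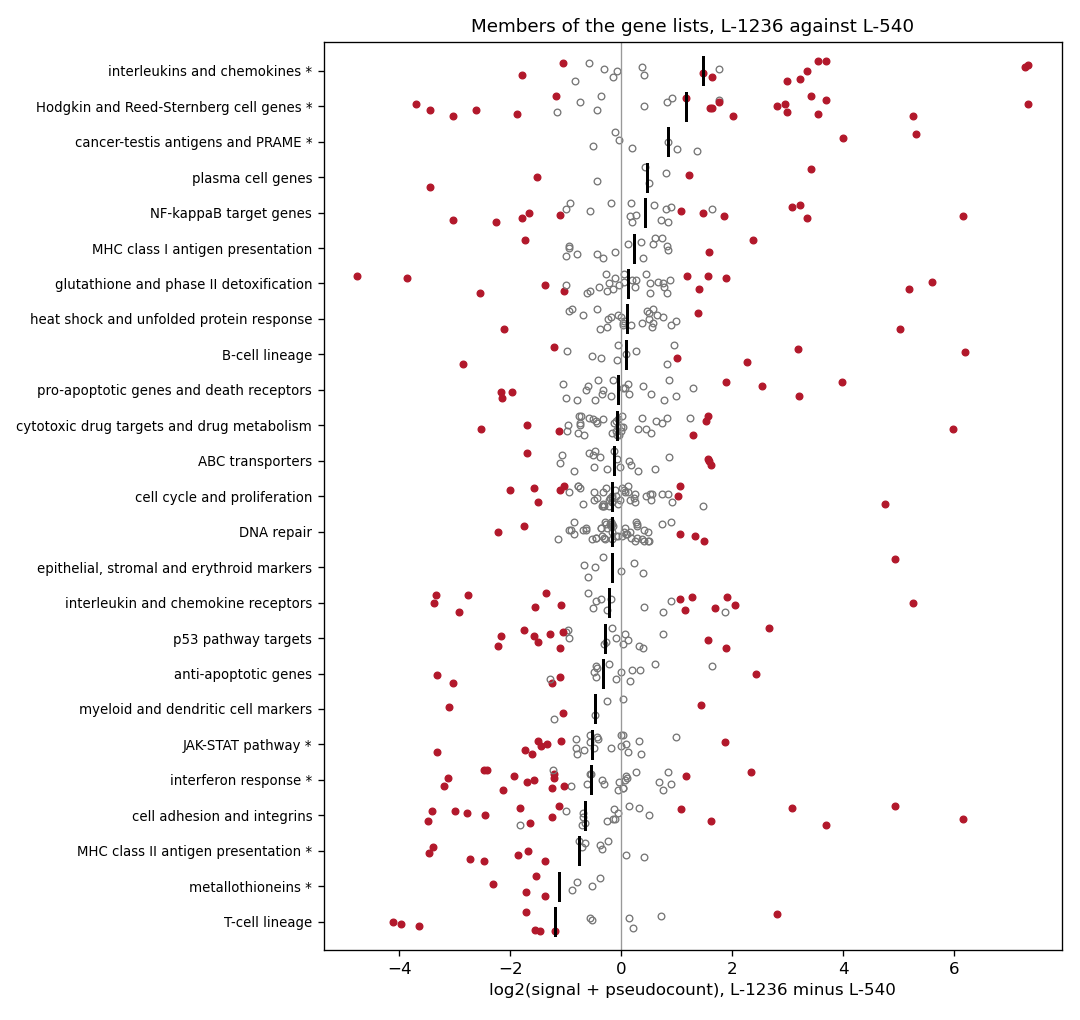
Difference in log2 signal between L-1236 and L-540 for the tested members of the 25 gene lists, with filled points for called genes, open points for the others, a bar at the median of each list and an asterisk at lists called by camera with its preset correlation. Medians ran from -1.20 for T-cell genes to 1.47 for interleukins and chemokines, and 7 lists carry the asterisk.

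Markers of cell lineage separated the lines gene by gene. Of 13 tested T-cell genes, 1 was higher in L-1236, 7 were higher in L-540 and 5 were not called, with 8 called when adjusted over the list alone (camera adjusted p = 0.0700). Higher in L-540 were GZMB (at least 16.1-fold, 7.80-fold and 33.1-fold without L-540 array 1 and 2) and PRF1 (log2 -3.97 ± 0.80 SE, -2.36 and -5.58 without L-1236 array 1 and 2), proteins of cytotoxic granules. CD247, the zeta chain of the T-cell receptor, was higher there as well (at least 13.7-fold, 6.31-fold and 29.7-fold without L-1236 array 1 and 2). GATA3, a transcription factor of T helper cells, was higher in L-1236 (log2 2.81 ± 0.20 SE). PRF1 read 109.5 and 1257 on the L-1236 arrays, and its limma adjusted p was 0.0555 without L-540 array 2. Without L-1236 array 2 the T-cell list was called lower in L-1236 by camera at its preset correlation only, where just the L-540 arrays gave a spread. That reading was made after the arrays had been seen. Of 15 tested B-cell genes, 4 were higher in L-1236, 2 were higher in L-540 and 9 were not called, with 6 called when adjusted over the list alone (camera adjusted p = 0.343). FCER2, the low-affinity IgE receptor (at least 35.2-fold), and POU2AF1 (at least 8.44-fold) and PAX5 (log2 2.28 ± 0.29 SE), regulators of B-cell transcription, were higher in L-1236. BLK, a kinase of B-cell receptor signalling, was higher in L-540 (at least 8.48-fold). Of 8 tested plasma cell genes, 2 were higher in L-1236, 2 were higher in L-540 and 4 were not called, with 4 called when adjusted over the list alone (camera adjusted p = 0.720). PRDM1, a regulator of plasma cell differentiation, was higher in L-540 (at least 9.33-fold, 6.19-fold and 14.1-fold without L-1236 array 1 and 2) and MZB1 in L-1236 (at least 9.66-fold). Of 7 tested myeloid and dendritic cell markers, 1 was higher in L-1236, 2 were higher in L-540 and 4 were not called, with 3 called when adjusted over the list alone (camera adjusted p = 0.343). CST3 was higher in L-540 (at least 9.93-fold, 5.36-fold and 18.4-fold without L-1236 array 1 and 2) with 73.7 and 281 on the L-1236 arrays. Of 8 tested epithelial, stromal and erythroid markers, 1 was higher in L-1236, 0 were higher in L-540 and 7 were not called, with 1 called when adjusted over the list alone (camera adjusted p = 0.936). PECAM1, an adhesion protein of endothelium and leukocytes, was higher in L-1236 (at least 32.2-fold), and the list had a median of -0.17, a mean of 0.43 and a downward test.

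Genes that handle drugs differed in single members, and none of their lists was called. Of 34 tested genes of glutathione and phase II detoxification, 6 were higher in L-1236, 5 were higher in L-540 and 23 were not called, with 11 called when adjusted over the list alone (camera adjusted p = 0.343). GSTM1 and GSTM2, near-identical glutathione transferases whose probe sets can share target, had signals of 16886 ± 2063 and 15964 ± 2634 (SD, n = 2) in L-1236 and 318 ± 13.6 and 410.3 ± 75.7 (SD, n = 2) in L-540. GSTO1 was higher in L-540 (log2 -3.87 ± 0.55 SE, -2.81 and -4.94 without L-1236 array 1 and 2). GSTP1 was too (log2 -1.03 ± 0.21 SE), with a limma adjusted p of 0.0789 without L-540 array 1 and a log2 difference of -0.98 without L-1236 array 1, where it was not called either. Of 21 tested ABC transporters, 3 were higher in L-1236, 1 was higher in L-540 and 17 were not called, with 4 called when adjusted over the list alone (camera adjusted p = 0.903). TAP1, a peptide transporter, differed by 1.58 ± 0.26 and ABCD3, a peroxisomal transporter, by 1.57 ± 0.29 (SE). ABCC1, a drug efflux pump, had a log2 difference of -0.13 ± 0.25 (SE; limma adjusted p = 0.762). ABCG2, another, was not called either (log2 -1.07 ± 0.46 SE, -0.32 and -1.82 without L-1236 array 1 and 2), with a limma adjusted p of 0.140. ABCG2 read 117 and 384 in L-1236, and was called without array 2, where only the L-540 arrays gave a spread. ABCB1 did not pass the filter. Of 40 tested drug targets and enzymes of drug metabolism, 4 were higher in L-1236, 3 were higher in L-540 and 33 were not called, with 7 called when adjusted over the list alone (camera adjusted p = 0.700, median -0.08, mean 0.02, test downward). CYP1B1, a cytochrome of xenobiotic metabolism, had a signal of 7650 ± 2864 (SD, n = 2) in L-1236 and 87.6 ± 12.5 (SD, n = 2) in L-540. The tubulin genes TUBA4A and TUBB2A differed by -2.53 ± 0.31 and 1.56 ± 0.28, and TYMP, thymidine phosphorylase, by -1.71 ± 0.30 (SE). TOP2A, the target of anthracyclines and etoposide, had a log2 difference of -0.33 ± 0.21 (SE; limma adjusted p = 0.305).

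Genes of cell death and DNA damage had called members in both directions. Of all 7724 tested genes 703 were called higher in L-1236 and 556 higher in L-540, so this is no trait of these lists. Of 18 tested anti-apoptotic genes, 1 was higher in L-1236, 4 were higher in L-540 and 13 were not called, with 5 called when adjusted over the list alone (camera adjusted p = 0.343). BCL2L1 had a signal of 3037 ± 143 (SD, n = 2) in L-1236 and 543 ± 33.2 (SD, n = 2) in L-540, a log2 difference of 2.42 ± 0.24 (SE). TRAF1 was higher in L-540 (at least 8.66-fold, 5.23-fold and 14.3-fold without L-1236 array 1 and 2). BCL2 and MCL1 had log2 differences of -0.10 ± 0.29 and -0.43 ± 0.23 (SE) and were not called. Of 28 tested pro-apoptotic genes and death receptors, 4 were higher in L-1236, 3 were higher in L-540 and 21 were not called, with 9 called when adjusted over the list alone (camera adjusted p = 0.855, median -0.06, mean 0.16, test upward). BNIP3 (at least 10.5-fold, 6.68-fold and 16.5-fold without L-1236 array 1 and 2), ENDOG (at least 4.86-fold) and BCL2L11 (at least 3.51-fold) were higher in L-1236. The death receptor TNFRSF10B differed by -2.16 ± 0.31 (SE). BAX, with 0.06 ± 0.34 (SE), was not called. Of 24 tested p53 pathway targets, 3 were higher in L-1236, 8 were higher in L-540 and 13 were not called, with 11 called when adjusted over the list alone (camera adjusted p = 0.162). PMAIP1 was higher in L-1236 (log2 1.89 ± 0.26 SE) and MDM2 in L-540 (at least 4.31-fold), the second with a limma adjusted p of 0.0776 without L-540 array 1. Of 53 tested DNA repair genes, 3 were higher in L-1236, 2 were higher in L-540 and 48 were not called, with 5 called when adjusted over the list alone (camera adjusted p = 0.700). FANCF, of the Fanconi anaemia pathway (at least 5.13-fold), and DDB2, which recognises ultraviolet damage (log2 -1.75 ± 0.29 SE), were higher in L-540. RAD23B, of nucleotide excision repair, stood at 2857 ± 841 (SD, n = 2) in L-1236 against 977 ± 168 (SD, n = 2) in L-540. Of 28 tested heat shock and unfolded protein genes, 2 were higher in L-1236, 1 was higher in L-540 and 25 were not called, with 3 called when adjusted over the list alone (camera adjusted p = 0.241). The chaperone HSPB1 stood at 6049 ± 832 (SD, n = 2) in L-1236 against 159.6 ± 56.4 (SD, n = 2) in L-540, and HSPA5 differed by 1.38 ± 0.20 (SE).

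The remaining lists were not called either. Of 26 tested NF-kappaB target genes, 7 were higher in L-1236, 5 were higher in L-540 and 14 were not called, with 13 called when adjusted over the list alone (camera adjusted p = 0.308). CD44, an adhesion receptor for hyaluronan, read 4124 ± 165 (SD, n = 2) in L-1236 and 34.9 ± 38.3 (SD, n = 2) in L-540. TNF (log2 3.35 ± 0.32 SE) and CXCL10 (log2 3.22 ± 0.55 SE, 2.25 and 4.20 without L-1236 array 1 and 2) were higher in L-1236. Of 29 tested genes of cell adhesion, 6 were higher in L-1236, 9 were higher in L-540 and 14 were not called, with 16 called when adjusted over the list alone (camera adjusted p = 0.468). ALCAM was higher in L-1236 (at least 15.2-fold) and SELPLG, a ligand of selectins, in L-540 (log2 -3.49 ± 0.51 SE, -2.55 and -4.43 without L-1236 array 1 and 2). Of 24 tested interleukin and chemokine receptors, 7 were higher in L-1236, 7 were higher in L-540 and 10 were not called, with 15 called when adjusted over the list alone (camera adjusted p = 0.903, median -0.22, mean -0.02, test upward). IL2RB (log2 -3.38 ± 0.47 SE, -2.51 and -4.25 without L-1236 array 1 and 2) and IL6R (at least 5.03-fold) were higher in L-540. IL2RB read 370.2 and 1305 on the L-1236 arrays. Of 50 tested genes of the cell cycle, 3 were higher in L-1236, 5 were higher in L-540 and 42 were not called, with 8 called when adjusted over the list alone (camera adjusted p = 0.609). CDKN2A, an inhibitor of cyclin-dependent kinases, was higher in L-1236 (at least 32.2-fold). Of 18 tested MHC class I genes, 2 were higher in L-1236, 1 was higher in L-540 and 15 were not called, with 3 called when adjusted over the list alone (camera adjusted p = 0.700), and HLA-E differed by -1.73 ± 0.27 (SE).

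The comparison of L-1236 with the mean of KM-H2 and HDLM-2 set lowest against intermediate sensitivity. CCL2 and FCER1A again led toward L-1236, at least 72.0-fold and 109-fold higher (limma adjusted p = 2.61e-05 and 2.61e-05), and CCL2 read 6.15 in KM-H2 and 14.8 in HDLM-2. MAOA, which degrades monoamines (at least 76.4-fold), BEX3 (at least 74.4-fold) and NDST4 (at least 81.7-fold) were also among the 5 largest. Toward the intermediate lines, ALOX5AP, of leukotriene synthesis, read 2301 in KM-H2 and 27726 in HDLM-2 against 11.3 and 215 on the L-1236 arrays. TPM2, a tropomyosin (at least 20.1-fold), and HLA-DRA (log2 -5.27 ± 0.56 SE, -4.16 and -6.39 without L-1236 array 1 and 2) were also higher there. The others of the 5 largest were DNAJC15 (at least 25.6-fold, 54.8-fold without KM-H2 and 11.9-fold without HDLM-2) and VAMP8, of vesicle fusion (at least 14.4-fold, 30.1-fold without KM-H2 and 6.89-fold without HDLM-2). Of the 15 MHC class II genes, 12 were lower in L-1236 (camera adjusted p = 6.25e-12, adjusted p = 0.821 with an estimated correlation). Of the 8 genes of the metallothionein list, 5 were lower (camera adjusted p = 9.52e-04, adjusted p = 0.821 with an estimated correlation), as were 8 of 33 interferon response genes (camera adjusted p = 0.00146, adjusted p = 0.821 with an estimated correlation). At the named metallothioneins the difference came from HDLM-2: MT2A read 2250.3 in KM-H2 and 16891 in HDLM-2, against 2075 ± 878 (SD, n = 2) in L-1236, and MT1X 627 and 6777, against 629 ± 468 (SD, n = 2). Genes at least 2-fold higher than in the other intermediate line numbered 6 of 8 in HDLM-2 and 0 in KM-H2 for this list, 17 of 33 in HDLM-2 and 7 in KM-H2 for interferon response and 6 of 15 in HDLM-2 and 2 in KM-H2 for MHC class II. Cell cycle genes were higher in L-1236 for 8 of 50 and lower for 1 (camera adjusted p = 0.0223, adjusted p = 0.821 with an estimated correlation). In all, 1165 genes differed, 729 higher and 436 lower in L-1236, and 1238 differed without L-1236 array 2. KM-H2 and HDLM-2 had 1 array each and were assumed to vary like the replicated lines, and the count was 738 without L-1236 array 1, 1935 without KM-H2 and 64 with sensitivity class as the factor.

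The comparison of the intermediate lines with L-540 gave cytokines and antigen presentation on the side of the intermediate lines. LTA (at least 56.9-fold, 160.3-fold without KM-H2 and 20.2-fold without HDLM-2) and CCL17 (at least 25.7-fold, 381-fold without KM-H2 and 1.74-fold without HDLM-2) had limma adjusted p of 7.56e-06 and 0.00148, with CCL17 at 172 in KM-H2 and 37648 in HDLM-2. TPM2 was at least 20.1-fold and PFKP, a phosphofructokinase of glycolysis, at least 32.0-fold higher, and HSPB1 differed by 5.02 ± 0.27 (SE). Toward L-540, NKG7 (at least 33.6-fold, 21.2-fold without KM-H2 and 53.2-fold without HDLM-2) and G0S2 (log2 -5.18 ± 0.63 SE) were among the 5 largest. GALNT14, a glycosyltransferase, had 2458 ± 59.5 (SD, n = 2) in L-540 against 18.4 in KM-H2 and 32.3 in HDLM-2, the last 2 under the level of background. DPP4, a surface peptidase, was also higher in L-540 (at least 23.1-fold, 48.7-fold without KM-H2 and 10.9-fold without HDLM-2), and RNF144A was at least 14.0-fold higher in L-540. Called members on the side of the intermediate lines numbered 11 of 19 interleukins and chemokines (camera adjusted p = 2.88e-06, adjusted p = 0.452 with an estimated correlation) and 14 of 27 Hodgkin and Reed-Sternberg cell genes (camera adjusted p = 2.10e-06, adjusted p = 0.452 with an estimated correlation). They numbered 9 of 15 MHC class II genes (camera adjusted p = 2.10e-06, adjusted p = 0.640 with an estimated correlation) and 11 of 26 NF-kappaB target genes (camera adjusted p = 2.07e-04, adjusted p = 0.640 with an estimated correlation). The intermediate lines were not alike here: genes at least 2-fold higher than in the other line numbered 17 of 27 in HDLM-2 and 2 in KM-H2 for Hodgkin and Reed-Sternberg cell genes and 8 of 19 in HDLM-2 and 3 in KM-H2 for interleukins and chemokines. Cancer-testis antigens had 5 of 9 higher (camera adjusted p = 0.00305, adjusted p = 0.640 with an estimated correlation), and cell cycle genes 10 of 50 lower in the intermediate lines (camera adjusted p = 0.00305, adjusted p = 0.640 with an estimated correlation). For cancer-testis antigens, 3 of 9 were at least 2-fold higher in KM-H2 than in HDLM-2 and 0 in HDLM-2. In all, 1213 genes differed, 512 higher in the intermediate lines and 701 higher in L-540. The count was 683 and 760 without L-540 array 1 or 2, 1826 without KM-H2 and 57 with sensitivity class as the factor.

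Whether the intermediate lines lay between the extremes was asked of the 1259 genes that separated L-1236 from L-540. BASP1 read 4739 in KM-H2 and 4712 in HDLM-2, between the means of L-1236 and L-540. Toward L-540, CYTIP read 551 and 598, SLC27A2, a fatty acid transporter, 729 and 375, and ENPP2, which makes lysophosphatidic acid, 1083 and 235. GLUL and PON2 were the others of the 5 largest ordered differences toward L-540. On L-1236 array 2 CYTIP read 944, ENPP2 349 and PON2 131, each above at least 1 intermediate line (PON2 read 163 in KM-H2 and 104 in HDLM-2). The order of these genes thus rested on L-1236 array 1, while GLUL and SLC27A2 kept it on array 2. BEX3, RGS2, RGS1 and RRAGD, the others of the 5 largest ordered differences toward L-1236, lost that order once signals under the level of background were set to it. Both intermediate lines lay between the 2 means at 374 genes (29.7%), 227 higher in L-1236 and 147 higher in L-540. With signals under the level of background set to it, 314 of these kept both lines between, 182 and 132. Taken singly, KM-H2 lay between at 680 and HDLM-2 at 653 of the 1259 genes. Both lay beyond L-540 at 82 genes and beyond L-1236 at 101. The genes were chosen for a wide gap, and no count was made for lines unrelated to sensitivity. The count of 374 is thus no evidence of an order with sensitivity. KM-H2 was nearer to L-1236 at 685 of the genes and nearer to L-540 at 574, and HDLM-2 at 599 and 660. With the 4 line means as the replicates, limma called 0 genes for a trend with sensitivity (smallest adjusted p = 0.99989), 217 had an unadjusted p under 0.05 where chance gives 386, and 34 were called without KM-H2. The ordered count was 656 without KM-H2 and 688 without HDLM-2, when 1 line fewer had to lie between.

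KM-H2 and HDLM-2 carry the same label of sensitivity, so a difference between them was not one of class, and with 1 array each it had no replicate check. CCL22, a chemokine that attracts regulatory T cells, read 15.6 in KM-H2 and 13763 in HDLM-2, at least 168-fold more, and CCL17 172 and 37648. S100A6, a calcium-binding protein, UCP2, a mitochondrial carrier, and PRDX2 were at least 109-fold, 86.1-fold and 59.3-fold higher in HDLM-2. Toward KM-H2, WNT5A, a secreted ligand, was at least 49.4-fold, CYB5R2 at least 36.9-fold, SPTBN1 at least 48.1-fold and MAGEB1 at least 47.6-fold higher, and MMP12, a macrophage elastase, read 11224 in KM-H2 and 122 in HDLM-2. Of 7724 genes, 3128 lay at least 2-fold apart, 1588 higher in KM-H2 and 1540 higher in HDLM-2, against 605 between the arrays of L-1236 and 616 between those of L-540.

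Genes bright in L-540 separated the 2 arrays of L-1236. At 39 genes the signal was 1000 or more on both L-540 arrays and under 100 on L-1236 array 1, and all 39 read higher on array 2. Their median was 14.9% of the L-540 mean on array 2 and 2.02% on array 1. PALLD, of the actin cytoskeleton, read 33.6 and 700.2, S100A6 74.4 and 596, and PLA2G2D 20.7 and 37.4. These genes were picked after their values were seen, and being picked for a low signal on array 1 can raise array 2 by itself. In the reverse direction, of 15 genes dim on array 2 and at 500 or more in L-540, 0 were raised by at least 1.5 log2 units on array 1, against 20 of 339 dim genes under that level in L-540.

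**Figure D3:**
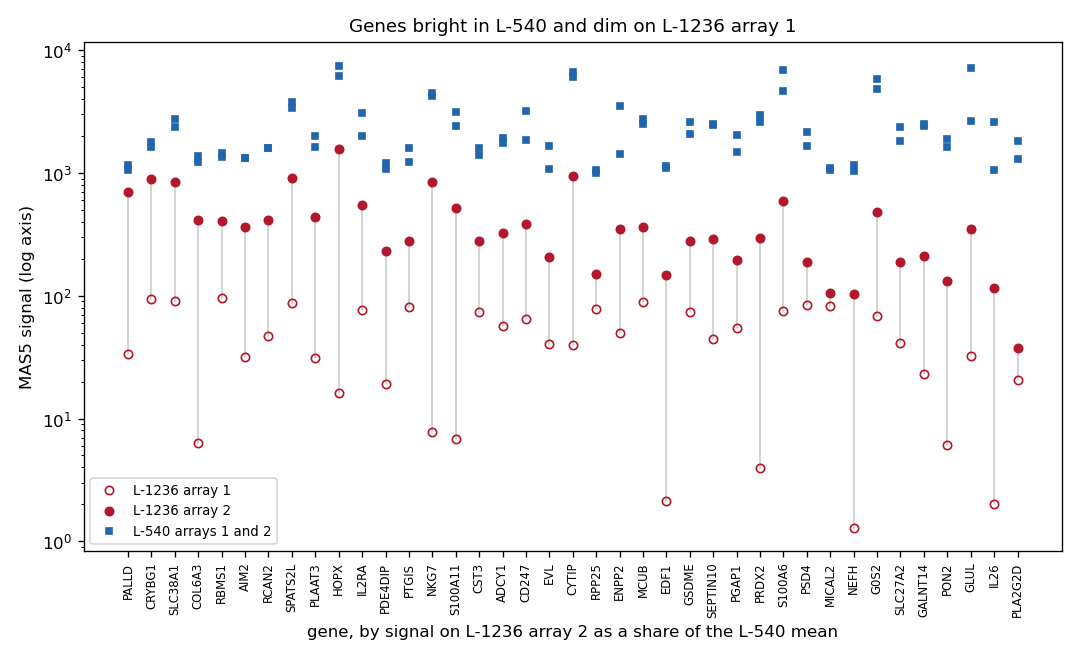
MAS5 signal (log axis) on the arrays of L-1236 (circles, open for array 1) and L-540 (squares) at the 39 genes bright in L-540 and dim on L-1236 array 1, ordered by the share of the L-540 mean that array 2 reached. Array 2 lay above array 1 at each gene, from 2.40% of the L-540 mean at PLA2G2D to 63.0% at PALLD.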

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

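The tests of RNA integrity, admixture and culture state were chosen only after their results or values that bear on them had been seen. Probe sets without exactly 1 gene symbol lay outside the comparisons, and 159 of 1440 that passed the filter differed between L-1236 and L-540, 94 higher in L-1236 and 65 higher in L-540.

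The 1259 genes called between L-1236 and L-540 could reflect drug sensitivity, lineage or RNA handling. Differences in RNA integrity are argued against by 3' to 5' control ratios, whose line difference was at most -0.102 on the log2 scale (GAPDH). Quantile normalization moved the share of calls higher in L-1236 by -0.717 percentage points. It makes the distributions of all arrays equal, and these arrays were already scaled alike. A shift made by global scaling itself can therefore not be judged from it. Differences of lineage stay open: across the called genes, which are not independent, KM-H2 minus HDLM-2 followed L-1236 minus L-540 with a Pearson r of 0.125, between the bounds set for and against. T-cell genes at least 2-fold higher than in the other intermediate line numbered 6 of 13 in HDLM-2 and 1 in KM-H2. B-cell genes numbered 4 of 15 in each. T-cell genes thus also differed within 1 class of sensitivity. With 1 line at each extreme, sensitivity and any other property of these lines cannot be told apart, and drug sensitivity itself was not tested.

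On L-1236 array 2, genes of L-540 stood at a median of 14.9% of their L-540 signal, and a candidate explanation is admixture of L-540 RNA or cells. Genes found only in L-540 reached 7.42% (4 genes), those found only in KM-H2 0.636% and only in HDLM-2 3.18%, but sets chosen as loosely as the first reached 5.67% and 7.15%. Mixing 1 line at a time gave best shares of 15% for L-540, 15% for KM-H2 and 12% for HDLM-2. Fit errors were not compared between the lines, so these shares cannot tell them apart. A joint regression tried afterwards gave 9.63%, 0.305% and 1.31%. It fitted array 2 from array 1 and the other lines, so any difference between the arrays that follows L-540 levels enters the L-540 share. With array 1 fitted from array 2 that share was -3.70%, which is not a possible amount of mixture. A culture state unrelated to L-540 stays open. Its first test found 51.6% of 155 genes raised on array 2 and 51.2% of all genes bright in L-540, 0.461 points apart. All genes include those already bright on array 1, which have less room to rise, so this test cannot decide. Among 38 genes raised on array 1, 15.8% were bright in L-540. The second test, adopted after the first outcome, found 56.4% of dim genes raised where L-540 was bright and 12.3% elsewhere. That gap of 44.1 points passed the bound set against a culture state, but with 1 array on each side. It was not computed for KM-H2 or HDLM-2. The sets chosen as loosely as the first read higher on array 2 at 74.1% of 54 genes for KM-H2 and 87.5% of 56 for HDLM-2, against all 39 for L-540. Without such a comparison the gap cannot decide on a culture state. FN1, SLA, ARHGAP29 and TSPAN13, picked after their values were seen, exceeded 1000 on array 2 without such signal in L-540. Admixture alone would not account for these genes, though 38 genes were raised by at least 1.5 log2 units on array 1 too.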

How the results depend on the processing

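The readings without L-1236 array 2 and the alternatives for KM-H2 against HDLM-2 were chosen after seeing the data, as was the rule of the fits without 1 array. Over all alternatives, 1827 of 1997 log2 differences between L-1236 and L-540, for 112 genes named for this comparison, for a list or by fixed choice, kept direction and side of the threshold. Of the others, 163 lost the call, 2 gained it, 5 changed sign without being called and 0 reversed while called. Of 447 values of the gene lists, 402 kept both, 15 lost the call, 5 gained it, 25 changed direction without being called and 0 reversed. Leaving out 1 array ended the call of 26 of 112 genes called between L-1236 and L-540 among all 128 named genes, in at least 1 fit. At an adjusted p under 0.01, a stricter threshold by construction, 685 genes differed between L-1236 and L-540 (396 higher, 289 lower), 520 between L-1236 and the intermediate lines (337 and 183), 532 between these and L-540 (223 and 309), and 234 were ordered. With sensitivity class as the factor, which takes KM-H2 against HDLM-2 as spread, the counts were 151 (116 and 35), 64 (50 and 14), 57 (32 and 25) and 80, and 1 list was called. Lists called numbered 4 without a filter, 0 with an estimated correlation, a test of little power here, and 1 by fry. The lists of interleukins and chemokines, cancer-testis antigens and interferon response were those lost without a filter, and the cause was not tested. Leaving out 1 array gave 820 to 1270 genes for L-1236 against L-540 (494 to 703 higher, 295 to 617 lower), 738 to 1935 for L-1236 against the intermediate lines (446 to 1175 and 292 to 760), 683 to 1826 for these against L-540 (345 to 742 and 338 to 1084), 280 to 688 ordered genes, 0 to 34 with a trend, and 5 to 7 lists. In fits without an array of L-1236 or L-540 the spread came from the other line's pair, so these ranges also reflect which pair was left. What a replicate number marks is not given in the labels. Deviations of same-numbered arrays had a correlation of -0.0167 across all genes, in 2 pairs, though the combined list of hypoxia and glycolysis genes had a higher median on array 1 in both lines. With a replicate block 1420 genes differed between L-1236 and L-540. Signals near the level of background limit what dim genes can show.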

Other observations

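All tests here were chosen after the arrays of each line had been compared. A combined list of genes induced by low oxygen and genes of glycolysis separated the arrays of a line, and genes of glycolysis were not tested by themselves. In L-540, DDIT4, an inhibitor of mTOR, read 6265 on array 1 and 608 on array 2, and HILPDA, a lipid droplet protein, 5764 and 557. HILPDA read 4503 and 1105 in L-1236, and ALDOC, an aldolase, 4342 and 1283. Of 30 genes, 15 were at least 2-fold higher on array 1 of L-540 and 8 on array 1 of L-1236. BNIP3 alone was at least 2-fold higher on array 2 of L-540. It read 4.98 and 65.7 on L-540 arrays 1 and 2, both under the level of background.

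Over the list the median log2 difference, array 1 minus array 2, was 0.42 in L-1236 and 1.04 in L-540, both at percentile 100 of random lists of like expression. Genes seen to differ had prompted the list, so after that outcome 7 members among the 100 genes farthest apart in either line were left out. The remaining 23 had medians of 0.28 and 0.56, and the lower of their percentiles among 10000 random lists was 99.99. A difference in oxygen supply or cell density between the cultures is a candidate explanation, with 1 array on each side in each line. These values fitted what had been written for it after the arrays had been compared. The labels give neither oxygen supply nor cell density, and other explanations were not tested.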
